A study of Homo sapiens with 12 samples.

How the data were processed

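Poly(A)-selected, stranded, paired-end RNA sequencing libraries with reads of 150 bases had been made from BC-3 cells, a human primary effusion lymphoma line that carries human herpesvirus 8 (HHV8). The cells carried a lentiviral vector with a doxycycline-inducible cassette for either MPH, a fusion of the MS2 coat protein (MCP) with the activation domains of p65 and HSF1, or hrGFPii, a green fluorescent protein used as the control. Per the labels, cells were plated at 400000 per ml, grown for 21 hours with 100 ng/ml or 0 ng/ml doxycycline and passed through a dead cell removal step before RNA extraction. The labels put 12 libraries in 4 groups of 3, which were named MPH uninduced, MPH induced, hrGFPii uninduced and hrGFPii induced. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

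The deposited table held 31680 rows and a column per library. Its values are a signal that the authors made from gene counts by scaling between libraries, and the table calls them normalised counts. The genome build was GRCh38, per the submitters' processing notes. The aligner, the counting tool, the annotation release and the formula of the scaling are not given in the sources used here. Whether the authors counted by strand is not given either, so antisense genes are reported as uncertain. Library totals of the normalised counts lay between 38722100 and 47251700. Low values piled up at multiples of a step in each library, between 0.777 and 1.18, which was read as the value of a single read. This step gave an estimate of 37900000 to 52400000 reads per library. Between 31.9% and 62.5% of the values under 10 lay within 0.03 reads of a whole number, where chance gives 6%. The rest lay between the steps, so whole reads were not recovered and count models were not applied. Whether the scaling differed between genes or reads had been counted in fractions was not tested. Intervals on reads cover counting error only.

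Of the 31680 rows, 31670 carried an Ensembl gene identifier. Symbols were found for 24437 of them in a table of gene names, matched without the version number, and 30650 were placed on GRCh38 with GENCODE release 29. Another 9 rows carried HHV8 identifiers, which no table used here pairs with gene names. The remaining row was named as unassigned, held at most 2.04e-05% of a library total and was left out of all tests.

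Values were analysed as log2(normalised count + 1) in R 4.3.3 with limma 3.58.1. A fold change is on that scale, which understates the change of genes with low values. Genes with a value of at least 10 in at least 3 libraries were tested, which left 17192. A linear model with a mean for each of the 4 groups was fitted to all 12 libraries, with empirical Bayes moderation and an intensity trend. Tests were two-sided and adjusted over the tested genes by the method of Benjamini and Hochberg. The threshold was an adjusted p under 0.05, and the count with at least a 2-fold change is given beside it. The 5 comparisons were MPH induced against uninduced, hrGFPii induced against uninduced, the difference between these inductions (the interaction), MPH against hrGFPii without doxycycline, and MPH against hrGFPii with doxycycline.

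Before the data were examined, 27 gene lists, the comparisons, the tests, the rule for named genes and most alternative settings had been written down. The lists covered heat shock, NF-kB targets, p53 targets, ATF4 and the integrated stress response, endoplasmic reticulum chaperones, pro-apoptotic and anti-apoptotic genes, the survival and IRF4 axis of primary effusion lymphoma, B cell identity, plasma cell identity, MYC targets with ribosome biogenesis, G1/S, G2/M, interferon-stimulated genes, cholesterol synthesis, immediate early genes, mitochondrially encoded genes, the nuclear-encoded respiratory chain, ribosomal proteins, replication-dependent histones, hypoxia with glycolysis, transcription coactivators, the NRF2 response, and markers of T and NK, myeloid, erythroid, and stromal or epithelial cells. RELA and HSF1 were kept out of the lists because the transgene holds parts of both. The lists share 19 genes. Each of the 25 lists with at least 5 tested members was tested against the other genes with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The myeloid list had 4 tested members and the erythroid list 2, so they were not tested.

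The rule for named genes took RELA and HSF1; the 12 largest rises and 12 largest falls for MPH induction and for the interaction, and 5 and 5 for the other comparisons, among genes with a symbol, past the threshold, with replicates that did not overlap and a mean of at least 100 in the higher group; up to 4 members of each list with the smallest adjusted p in MPH induction; a fixed set of IRF4, MYC, MCL1, CFLAR, CCND2, MDM2, CDKN1A, NFKBIA, HSPA1A, HSPA1B and DNAJB1 whatever their test; and the viral rows. HSPA1A and HSPA1B, TRBC1, HBA1, FRG2B and the pseudogene RPS27AP16 have near-identical copies, and their values are uncertain because the authors' counting could split reads between copies.

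The fit was tested on simulated libraries with 16654 tested genes. All genes were given the same dispersion of 0.001, and few were changed, in the MPH induced libraries alone, while 58.5% passed in the data. The shares below hold for that setting and do not measure recovery or false calls where the spread differs between genes. For MPH induction it recovered 63.3% of genes changed 1.25-fold, 76.6% at 1.5-fold, 87.5% at 2-fold and 97.9% at 4-fold, and called 3 of 16462 unchanged genes. For the interaction it recovered 55.1%, 70.2%, 83.3% and 93.8% at the same folds and called 8 of 16462 unchanged genes. In that simulation a list shifted 1.5-fold was called, and 1 of 25 unshifted lists was called too.

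The alternatives were pseudocounts of 0.5 and 5, no filter, a filter of 50, rescaling with TMM factors computed on the tested genes, the replicate number as a block, only the compared groups in the fit, no intensity trend, and each replicate left out in turn. Rescaling to equal totals per library, thinning of the estimated reads to the depth of the shallowest library, and a filter on the hrGFPii libraries alone for the relation with abundance, were added after the data had been seen. The overlap of comparisons that share libraries was set beside 100 simulations of unchanged groups, and after the data had been seen beside another 100 for the filter of 50. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.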

Results

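RNA was sequenced from BC-3 cells, a primary effusion lymphoma line latently infected with HHV8, that carried an inducible cassette for MPH or for hrGFPii. MPH joins the MS2 coat protein to the activation domains of p65 and HSF1 and is the activator component of a CRISPR activation system; hrGFPii is a fluorescent control protein. Each vector was sampled without doxycycline and after 21 hours with 100 ng/ml doxycycline, with 3 libraries in each of the 4 groups. Normalised counts summed to between 38722100 and 39147600 in the MPH induced libraries and to between 44756100 and 47251700 in the other 9. Rows with a value of 0 made up 22.4 ± 0.995% of the MPH induced and 27.3 ± 0.367% of the MPH uninduced libraries (SD, n = 3 each), and mitochondrially encoded genes 6.50 ± 0.360% and 5.77 ± 0.255% of their totals. Libraries of a group had a Pearson r of log2 values between 0.984 and 0.990 across genes, which are not independent replicates. Principal components were computed on the 12112 genes with at least 50 normalised counts in all 12 libraries, so genes with low values did not enter. The first held 73.8% of the variance of these genes. It placed the MPH induced libraries between 41.0 and 42.5, the hrGFPii induced libraries between -6.49 and -5.58, and the uninduced libraries of both vectors between -19.0 and -17.4.

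**Figure D1:**
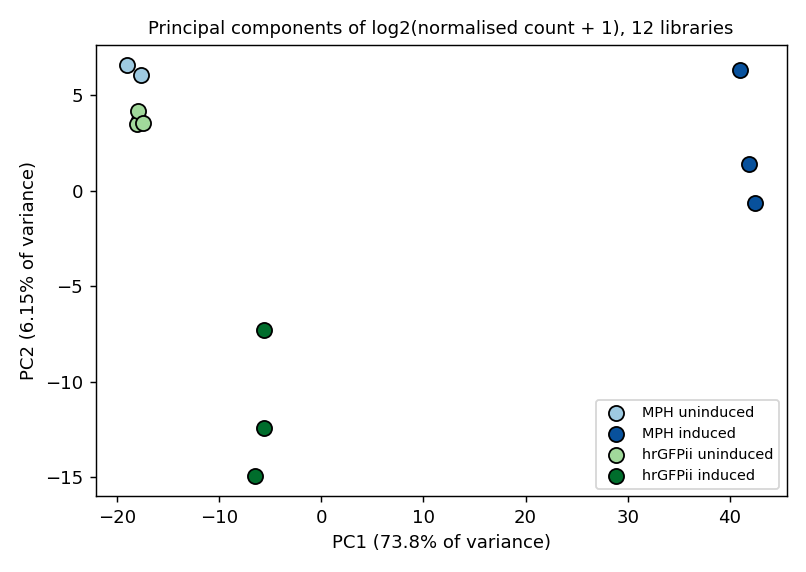
Principal components of log2(normalised count + 1) over the 12 libraries, with a point per library coloured by group. They were computed on the 12112 genes with at least 50 normalised counts in all libraries. PC1, in units of the component score, separates the MPH induced libraries (41.0 to 42.5) from the other 9, and the hrGFPii induced libraries lie between those and the uninduced libraries.

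HSF1 and RELA were examined first, because reads of the MPH transgene can fall on either gene. HSF1 (ENSG00000185122.11, chromosome 8, 144291591 to 144314722, GRCh38) stood at 3356 ± 36.1 normalised counts in MPH uninduced cells and at 14330 ± 343 in MPH induced cells (SD, n = 3 each), a log2 change of 2.09 (SE 0.0389, adjusted p = 2.22e-13 by limma). In hrGFPii cells it stood at 3323 ± 51.4 without and 3444 ± 182 with doxycycline, a log2 change of 0.051 with an adjusted p of 0.449. RELA, which encodes p65 (ENSG00000173039.19, chromosome 11, 65653596 to 65663094), fell from 3263 ± 275 to 2602 ± 85.8 after MPH induction, by 0.32 on the log2 scale (adjusted p = 0.000513). The call of RELA was lost when libraries were rescaled to equal totals, at a log2 change of -0.0545 (adjusted p = 0.454). Without doxycycline neither gene passed the threshold between the vectors, with log2 differences of 0.0145 for HSF1 (adjusted p = 0.955) and -0.0108 for RELA (adjusted p = 0.986).

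**Figure D2:**
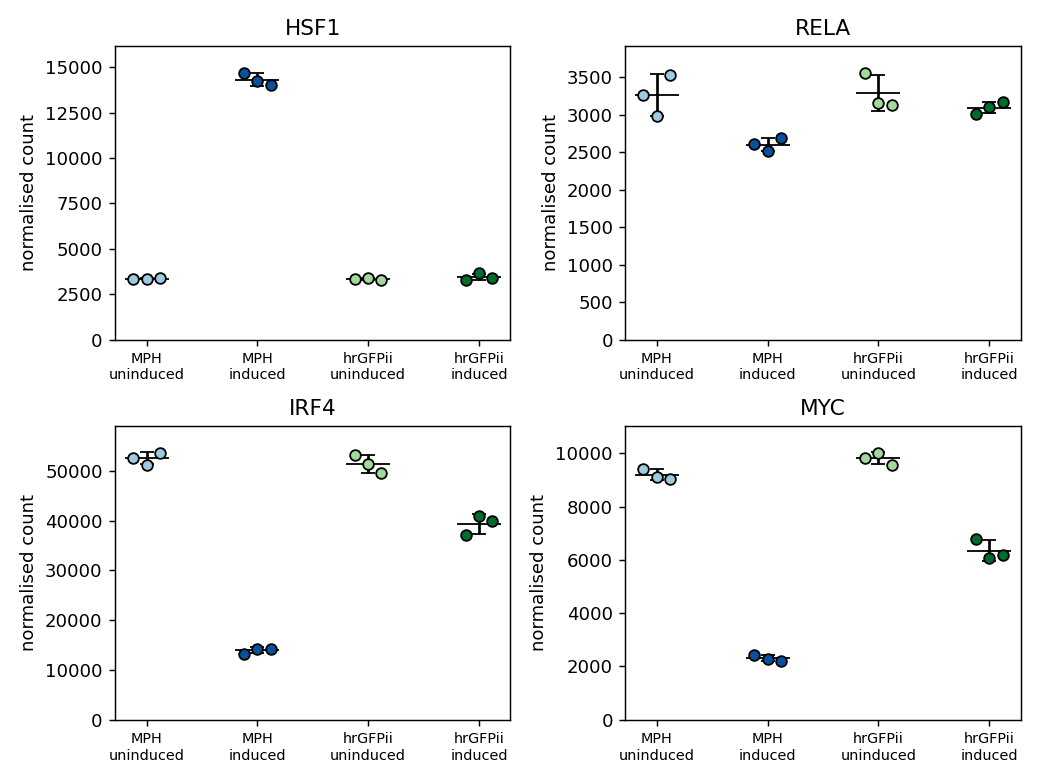
Normalised counts of HSF1, RELA, IRF4 and MYC in each library, by group, with the group mean and SD as bars (n = 3) and axes that start at 0. HSF1 is at 14330 in MPH induced cells against 3323 to 3444 in the other groups, while IRF4 and MYC are lowest in MPH induced cells and lower in hrGFPii induced than in hrGFPii uninduced cells.

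Transcription factors and survival genes that characterise this lymphoma were lower after MPH induction. Part of this was also seen with doxycycline and hrGFPii, where IRF4, MYC and CCND2 changed by -0.39, -0.63 and -0.73 on the log2 scale. IRF4 (chromosome 6, 391739 to 411447), the master regulator of plasma cell fate, fell from 52490 ± 1210 to 13930 ± 601 normalised counts, 3.77-fold. MYC (chromosome 8, 127735434 to 127741434) fell from 9203 ± 198 to 2305 ± 108, and cyclin D2 (CCND2) from 22480 ± 267 to 4877 ± 42.2. The apoptosis inhibitors MCL1 and CFLAR fell by 1.22 and 1.15 on the log2 scale, MDM2 fell by 0.64 and CDKN1A by 0.76. The difference of MDM2 between the inductions, -0.37 (adjusted p = 0.000555 by limma), was lost with equal totals per library (-0.15, adjusted p = 0.0818). In the list of the survival and IRF4 axis, 14 of 17 tested genes fell and 2 rose (camera adjusted p = 3.23e-08). All 14 tested members of the plasma cell identity list, called plasma cell genes below, fell (camera adjusted p = 5.57e-10), with a median log2 change of -1.63. Among these list members the transcription factor XBP1 fell by 1.82 and TNFRSF8, which encodes CD30, by 2.03. The surface receptor SLAMF7, also on the list, fell from 19430 to 6873 normalised counts.

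In all, 10055 of 17192 tested genes passed the threshold between MPH induced and uninduced cells, 4837 higher and 5218 lower. At least 2-fold changes were found for 2255 genes, 1473 higher and 782 lower. The number with at least 2-fold change was 1452 with the filter at 50. The direction of small changes rested on the scaling. With equal totals per library all log2 changes shifted by 0.27, and 74.1% of the changed genes were then higher, against 48.1% on the deposited scale.

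The genes with the largest rises started from low values. DNAH12, a dynein heavy chain of cilia, rose from 13.5 ± 2.36 to 215.9 ± 73.6 normalised counts, a log2 change of 3.86. The homeobox gene MEIS3 rose from 7.58 ± 1.43 to 117.4 ± 17.6, the extracellular matrix gene PAPLN from 18.9 ± 5.22 to 233.6 ± 13.7, and the calpain gene CAPN6 from 38.6 ± 2.49 to 412.3 ± 7.97. RAB3B and RAB6B, which encode small GTPases of vesicle transport, rose by 3.20 and 3.36 on the log2 scale, the helicase gene DDX60 by 3.35, and the chromatin organiser SATB1 by 3.40. ZMAT1, REPS2, CCDC136 and ZFHX2 completed the 12 largest rises, with log2 changes between 3.10 and 3.39. The largest falls included THBS1, which encodes the matrix protein thrombospondin and was at 129.2 ± 8.67 normalised counts after induction (log2 change -3.62). The organic anion transporter SLCO4A1 was at 186.7 ± 16.4 before induction (log2 change -3.46), and the class II transactivator CIITA fell from 1111 ± 7.06 to 178.9 ± 22.1. The cytokine IL10 fell by 2.95 on the log2 scale, MYCN by 2.74, the chemokine receptor CCR2 by 2.62, the phosphatase PTP4A3 by 2.64 and PLAAT2 by 2.60. DNAJC5B, FAM30A and TRBC1 fell by 3.12, 3.00 and 3.35, of which TRBC1 has a near-identical copy. ACTL10 went from 347.2 ± 48.1 to 23.6 ± 41.0; it stood at 0 in 2 of the 3 induced libraries and at 70.9 in the other, so the size of its fitted fall, -6.38 (SE 1.14), depends on the pseudocount and is uncertain.

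Growth-related genes fell together. All 28 MYC target and ribosome biogenesis genes fell (camera adjusted p = 2.04e-17), with a median log2 change of -1.05; spermidine synthase (SRM) fell by 1.43, the nucleolar proteins NOP56 and NOLC1 by 1.21 and 1.19, and ornithine decarboxylase (ODC1) by 1.13. All 38 cytosolic ribosomal protein genes fell (adjusted p = 2.04e-17), with a median of -0.49 and RPS2 at -0.71. The list tests here and below were not matched for abundance. All genes with a mean above 20000 normalised counts had a median of -0.53, and those between 5000 and 20000 of -0.26. Whether lists of abundant genes fell beyond this was not tested. All 23 G2/M genes fell (adjusted p = 4.15e-11), among them MKI67 by 0.88, CCNB1 by 0.89 and UBE2C by 0.97. Of 26 G1/S genes, 23 fell and 0 rose (adjusted p = 4.15e-11), led by the ribonucleotide reductase subunit RRM2, which fell by 1.53 on the log2 scale, and by MCM7, PCNA and FEN1. Replication-dependent histones were not called as a list, with 4 of 16 lower and 2 higher (adjusted p = 0.816), or 3 lower and 5 higher with equal totals. With equal totals 27 MYC targets and 36 ribosomal protein genes were lower and 0 higher, 17 G2/M genes were lower and 1 higher, and 20 G1/S genes lower and 3 higher.

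Metabolic lists were lower as well. Of 23 cholesterol synthesis genes, 21 fell and 1 rose (adjusted p = 1.19e-07), against 16 lower and 2 higher with equal totals, including INSIG1 with a log2 change of -1.63. In the hypoxia and glycolysis list, 14 of 23 fell and 3 rose (adjusted p = 0.0019), or were lower in 11 and higher in 7 with equal totals, including LDHA at -1.17, hexokinase 2 (HK2) at -1.31 and GAPDH at -0.83. Of 28 nuclear-encoded respiratory chain genes, 23 fell and 1 rose (adjusted p = 3.37e-06), with CYC1 at -1.09; with equal totals 10 were lower and 8 higher, with a median of -0.007. Of 13 mitochondrially encoded genes, 8 fell and 0 rose (adjusted p = 0.028), but the call was lost with an estimated correlation (adjusted p = 0.425) and the median of -0.16 became 0.11 with equal totals per library. It was also lost without MPH uninduced replicate 3 (adjusted p = 0.0899) or MPH induced replicate 1 (adjusted p = 0.059) or 2 (adjusted p = 0.0657), and with the filter at 50 (adjusted p = 0.0739).

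Stress and signalling lists also moved down. Heat shock genes fell in 21 of 25 cases and rose in 3 (adjusted p = 8.59e-07), or were lower in 12 and higher in 7 with equal totals: HSPA8 fell from 236400 to 115400 normalised counts, HSPD1 by 1.08 on the log2 scale and HSP90AA1 by 0.75. The near-identical genes HSPA1A and HSPA1B showed log2 changes of -0.12 and -0.13, which became 0.15 and 0.13 with equal totals, and the cochaperone DNAJB1 fell by 0.30, a call lost with equal totals (adjusted p = 0.458). HSPA1A did not pass without MPH uninduced replicate 3 (adjusted p = 0.0641) or MPH induced replicate 2 (adjusted p = 0.0733). Of 24 NF-kB targets, 18 fell and 2 rose (adjusted p = 2.58e-06), including the inhibitor NFKBIA at -1.02, the chemokine receptor CCR7 at -2.40 and lymphotoxin beta (LTB) at -2.02. Of 29 genes of ATF4 and the integrated stress response, 18 fell and 1 rose (adjusted p = 1.06e-05), with ATF4 itself at -1.05 and the amino acid transporter SLC7A5 at -1.53. Of 22 endoplasmic reticulum chaperone and unfolded protein response genes, 16 fell and 0 rose (adjusted p = 1.42e-06), but 13 were lower and 6 higher with equal totals, with HSPA5 at -0.93 and HERPUD1 at -1.34. Immediate early genes had 11 of 22 lower and 4 higher (adjusted p = 0.0161), with KLF2 at -2.54 and JUNB at -1.17; that call was lost with an estimated correlation (adjusted p = 0.139). In the anti-apoptotic list 7 of 11 fell and 1 rose (adjusted p = 0.00103), with BIRC5 at -1.02 and BCL2 at -0.91. With equal totals 16 NF-kB targets were lower and 3 higher, 17 and 5 genes of ATF4 and the integrated stress response, 10 and 5 immediate early genes, and 7 and 4 anti-apoptotic genes.

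Interferon-stimulated genes were the list that rose. Of 27 tested members, 20 rose and 5 fell (adjusted p = 0.000369), with a median log2 change of 0.80. OAS3 rose from 393.7 to 1918 normalised counts and IFIT5 from 39.5 ± 8.80 to 245.0 ± 34.5. The 5 members that fell were those with the highest values in uninduced cells: OAS2 went from 15560 to 8255, BST2 from 20280 to 12650 and ISG20 from 3247 to 1202, and STAT2 had a log2 change of -0.21. With equal totals 23 members were higher and 3 lower, with a median of 1.07.

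The other lists were not called with camera. Of 25 p53 targets, 8 rose and 12 fell (adjusted p = 0.566), of 18 pro-apoptotic genes 5 rose and 11 fell (adjusted p = 0.0883), of 9 B cell identity genes 3 rose and 6 fell (adjusted p = 0.0646), of 24 coactivator and elongation genes 8 rose and 6 fell (adjusted p = 0.847), and of 18 NRF2 response genes 4 rose and 8 fell (adjusted p = 0.118). Within them AEN fell by 1.24 on the log2 scale, the antigen presentation gene HLA-DRA by 1.29 and the ferritin light chain FTL by 1.01. Among markers of other cells, 1 of 6 T and NK cell genes fell (adjusted p = 0.847), and 5 of 10 stromal and epithelial genes fell and 1 rose (adjusted p = 0.238), with CDH1 at -1.55 and EPCAM at -0.93. The coactivator list was placed upwards by camera while its median was -0.070, and the stromal list had a median of -0.27 and a mean of 0.052. B cell identity was called downwards with equal totals (adjusted p = 0.029) and without MPH uninduced replicate 2 (adjusted p = 0.0494). With equal totals the medians of the p53, pro-apoptotic, coactivator, NRF2, and T and NK lists turned positive. The balance of calls turned in the p53 (12 higher, 6 lower), pro-apoptotic (7 and 6), NRF2 (7 and 6), and T and NK (2 and 1) lists. The coactivator list had 15 higher and 3 lower. The myeloid and erythroid lists, with 4 and 2 tested members, held no group mean above 58.2 and 439.2 normalised counts; the highest was the globin gene HBD, which fell by 1.59 on the log2 scale.

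Adjusted over the list alone, the counts for MPH induction were 3 higher and 19 lower for NF-kB targets, 1 and 16 for endoplasmic reticulum chaperones, 1 and 8 for anti-apoptotic genes, 2 and 15 for the survival and IRF4 axis, and 1 and 24 for the respiratory chain; the other 20 lists had the counts given above. Of the 17 lists called, the other 15 also held with an estimated correlation, at adjusted p-values of up to 0.04.

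**Figure D3:**
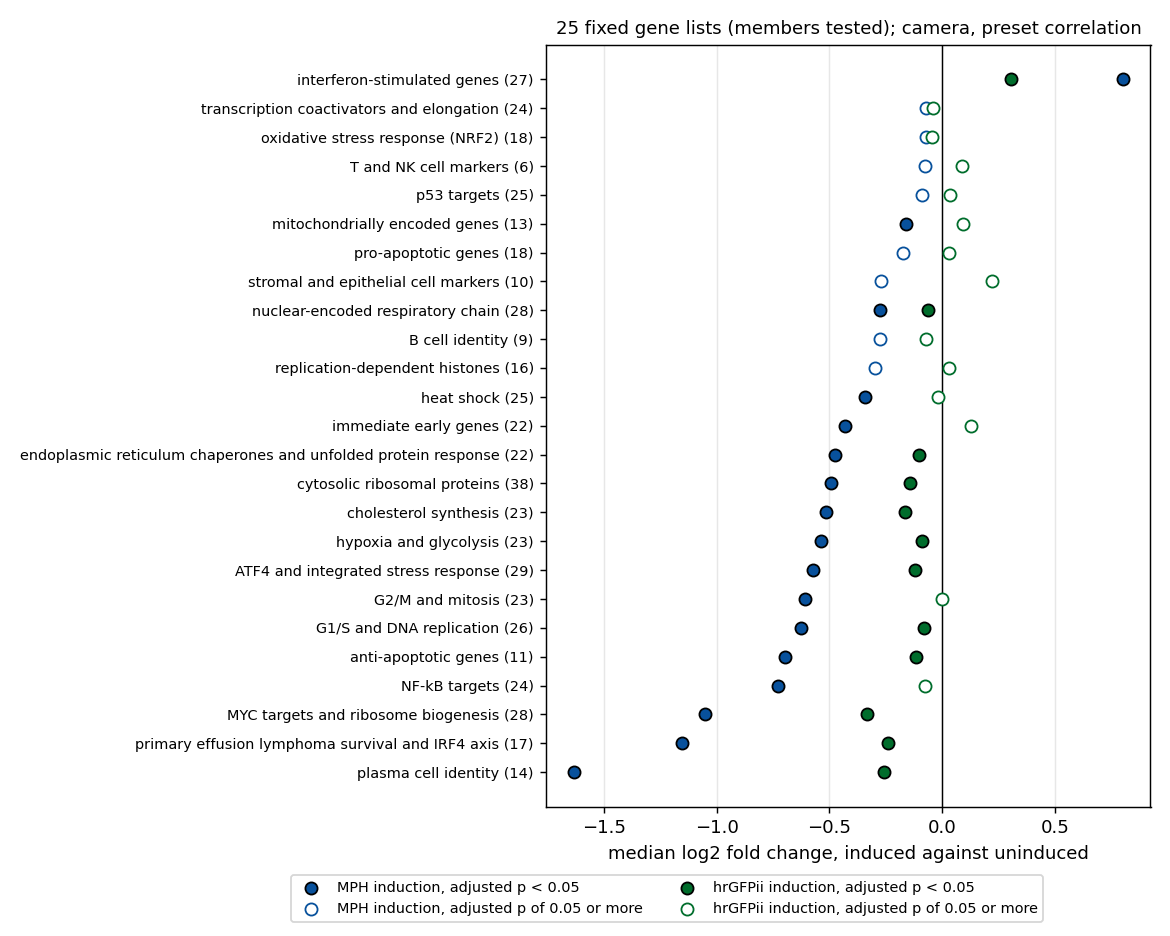
Median log2 fold change of the members of each of the 25 tested lists, induced against uninduced, for MPH (blue) and hrGFPii (green); filled points have a camera adjusted p under 0.05 at the preset correlation, and numbers in parentheses give the members tested. Plasma cell identity has the lowest MPH median, -1.63, and interferon-stimulated genes the highest, 0.80; with equal totals per library the MPH medians of the mitochondrially encoded, p53, pro-apoptotic, coactivator, NRF2, and T and NK lists change sign, and so do the hrGFPii medians of heat shock, G2/M, coactivator and NRF2 genes.

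Viral transcripts were measured on 9 rows with HHV8 identifiers. Their summed normalised count fell from 9434 ± 281 in MPH uninduced to 3904 ± 308 in MPH induced libraries (SD, n = 3). In hrGFPii cells the sum was 10320 ± 252 without and 8021 ± 189 with doxycycline. Most of the sum in each group lay on the row HHV8GK18_gp79, which fell from 6036 to 2144 in MPH cells and from 6792 to 5405 in hrGFPii cells. Of the 7 rows that could be tested, 6 fell and 1 rose after MPH induction, and 4 fell and 0 rose after hrGFPii induction. With equal totals the fall of HHV8_gs01 in MPH cells was lost (log2 change -0.21, adjusted p = 0.127). The difference between the inductions passed the threshold for 5 of the 7, all of which fell more in MPH cells. It did not for HHV8_gs01, which changed by -0.48 in MPH and -0.45 in hrGFPii cells (adjusted p of the difference 0.905 by limma). The row HHV8GK18_gp62 fell from 415.1 to 65.7 normalised counts in MPH cells, a log2 change of -2.64, and HHV8GK18_gp64 from 719.7 to 133.2, a log2 change of -2.43. The row that rose, HHV8GK18_gp01, went from 9.45 to 32.4, a log2 change of 1.75.

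**Figure D4:**
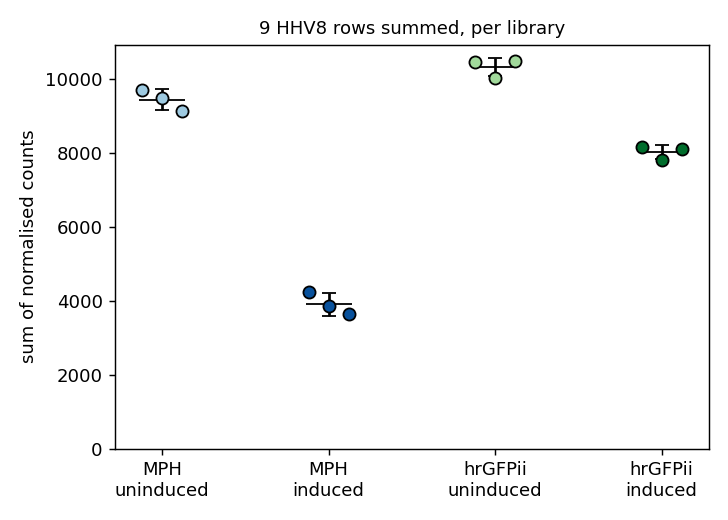
Sum of the normalised counts of the 9 HHV8 rows in each library, by group, with the mean and SD (n = 3) and an axis that starts at 0. The sum is 3904 in MPH induced cells against 9434 in MPH uninduced cells, and 8021 against 10320 in hrGFPii cells. Most of it lies on the row HHV8GK18_gp79 in each group.

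Doxycycline with the control protein gave a smaller response. In hrGFPii cells IRF4 fell from 51370 ± 1730 to 39280 ± 2010 normalised counts (log2 change -0.39, adjusted p = 9.28e-05), MYC fell by 0.63 and CCND2 by 0.73 on the log2 scale. Interferon-stimulated genes rose, 15 of 27 with 1 lower (camera adjusted p = 8.44e-12): IFIT5 rose from 32.6 ± 9.69 to 112.6 ± 19.9 and OAS3 from 364.5 to 797.1. DTX3L, a ubiquitin ligase gene, rose from 106.0 ± 28.7 to 343.0 ± 8.96. CSMD3, C2orf50 and the aldo-keto reductase AKR1C2 also rose, by 2.31, 2.17 and 2.15 on the log2 scale. TNFRSF13B, which encodes the TACI receptor of B cells for BAFF and APRIL, the interleukin receptor IL6R, RGS16 and AQP4-AS1, an antisense gene and so uncertain, fell, with log2 changes of -0.92, -0.91, -0.91 and -0.94. FLNC was lower by a log2 change of -0.95 (adjusted p = 0.0175), a call lost in the fit with only the compared groups (adjusted p = 0.0686) and without hrGFPii uninduced replicate 1 (adjusted p = 0.065) or 2 (adjusted p = 0.0532) or hrGFPii induced replicate 2 (adjusted p = 0.0673) or 3 (adjusted p = 0.0763).

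Of the lists, MYC targets and ribosome biogenesis fell in 26 of 28 genes in hrGFPii cells (adjusted p = 4.57e-30) with a median log2 change of -0.33, and ribosomal proteins in 30 of 38 (adjusted p = 2.25e-20) with a median of -0.14. With equal totals 25 of the 28 and 15 of the 38 were lower, and none was higher. The survival and IRF4 axis had 11 of 17 lower and 1 higher (adjusted p = 9.6e-09), plasma cell genes 9 of 14 lower (adjusted p = 2.76e-06), cholesterol synthesis 13 of 23 lower (adjusted p = 2.57e-08), and ATF4 and the integrated stress response 10 of 29 lower (adjusted p = 0.000403); with equal totals 11, 9, 9 and 7 were lower in these lists. Another 5 lists were called downwards and lost with an estimated correlation: endoplasmic reticulum chaperones (8 of 22 lower, 1 higher; adjusted p = 0.128 with an estimated correlation), anti-apoptotic genes (4 of 11 lower, 1 higher; 0.133, and 0.0874 without hrGFPii induced replicate 1 and 0.0681 with equal totals), G1/S (7 of 26 lower, 1 higher; 0.128), the respiratory chain (6 of 28 lower; 0.0891) and hypoxia with glycolysis (7 of 23 lower, 1 higher; 0.061), each value being an adjusted p. Heat shock genes were not called in hrGFPii cells, with 7 of 25 higher and 4 lower (adjusted p = 0.714), a median of -0.018, which was 0.031 with equal totals, and a mean of 0.035; HSPA1A and DNAJB1 were among those that rose, by 0.29 and 0.20 on the log2 scale. Adjusted over the list alone, the counts were 28 lower for MYC targets, 36 for ribosomal proteins, 12 lower and 1 higher for the survival axis, 9 for plasma cell genes, 15 lower and 1 higher for cholesterol synthesis, 10 for ATF4, and 18 higher and 2 lower for interferon-stimulated genes; those of the 5 lists lost with an estimated correlation were 11 lower and 2 higher, 6 and 1, 12 and 1, 7 and 0, and 11 and 2 in the order given.

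In hrGFPii cells 2233 genes passed the threshold, 932 higher and 1301 lower, and 97 changed at least 2-fold, 74 higher and 23 lower. The count was 1383 when only the compared groups entered the fit and 1444 without hrGFPii induced replicate 3, where 64 changed at least 2-fold. With equal totals 66.6% of the changed genes were higher, against 41.7% on the deposited scale.

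The interaction asked which genes responded differently to doxycycline in MPH and hrGFPii cells. The 6639 genes past the threshold comprised 2681 with a higher and 3958 with a lower response in MPH cells, and 1266 differed at least 2-fold, 748 higher and 518 lower. HSF1 differed by a log2 value of 2.04 (adjusted p = 8.68e-11), IRF4 by -1.53 (adjusted p = 6.02e-10), MYC by -1.37 (adjusted p = 2.86e-09), CCND2 by -1.47 and MCL1 by -1.07. RAB6B, MEIS3, the dynamin gene DNM1, DNAH6 and DNAH12 had the largest positive differences, between 3.31 and 4.95 on the log2 scale, followed by CCDC9B, CAPN5, ZFHX2, PAPLN, REPS2, ZMAT1 and LPCAT2, between 2.71 and 3.20. None of these genes passed the threshold in hrGFPii cells. There RAB6B went from 52.4 to 16.1 normalised counts, DNAH6 from 25.1 to 6.74 and CCDC9B from 75.6 to 32.1, which adds to their differences. MEIS3, DNAH12, PAPLN, REPS2 and ZMAT1 had positive log2 changes there instead. The rule on overlapping replicates covered the MPH groups alone, so the sizes are uncertain. The largest negative differences, apart from ACTL10 with its uncertain -5.93 (SE 1.62), were those of SLCO4A1 at -3.22, THBS1 at -3.10, TRBC1 at -2.92, PTP4A3 at -2.54, CIITA at -2.51 and IL10 at -2.51. The integrin gene ITGAL, the myosin gene MYO1F, CCR2, PLAAT2 and FRG2B, which has near-identical copies, differed by between -2.42 and -2.35. With equal totals 72.7% of the genes that differed were higher, against 40.4% on the deposited scale.

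As lists, plasma cell genes responded more negatively in MPH cells in 13 of 14 cases (camera adjusted p = 6.27e-12), G2/M genes in 22 of 23 (adjusted p = 5.72e-15), G1/S genes in 24 of 26 (adjusted p = 6.29e-14), MYC targets in 26 of 28 (adjusted p = 1.47e-16), ribosomal proteins in 36 of 38 (adjusted p = 7.24e-16), heat shock genes in 20 of 25 with 2 opposite (adjusted p = 2.44e-09), and NF-kB targets in 18 of 24 with 2 opposite (adjusted p = 1.3e-07). With equal totals, more negative responses numbered 13 for plasma cell genes, 18 for G2/M, 20 for G1/S with 1 opposite, 22 for MYC targets, 23 for ribosomal proteins, 14 for heat shock genes with 4 opposite, and 17 for NF-kB targets with 3 opposite. The rise of interferon-stimulated genes was not shown to differ between the vectors as a list, with 11 of 27 higher and 5 lower in the interaction (adjusted p = 0.147). With equal totals 17 were higher and 4 lower, with a median of 0.50, and the list was still not called (camera adjusted p = 0.254). In total 18 lists were called, all downwards, of which 3 were lost with an estimated correlation, namely pro-apoptotic genes (adjusted p = 0.0682), B cell identity (adjusted p = 0.091) and mitochondrially encoded genes (adjusted p = 0.298). The respiratory chain had a median of -0.19, which became 0.032 with equal totals, where its call was lost (adjusted p = 0.111). So were the calls of mitochondrially encoded (adjusted p = 0.249) and pro-apoptotic genes (adjusted p = 0.0885), the latter also with the filter at 50 (adjusted p = 0.0947). Without MPH uninduced replicate 3 the calls of pro-apoptotic genes (adjusted p = 0.0525) and B cell identity (adjusted p = 0.0562) were lost, the former also without MPH induced replicate 3 (adjusted p = 0.0519). Adjusted over the list alone, 14 plasma cell genes were lower, 21 heat shock genes were lower and 3 higher, and 12 interferon-stimulated genes were higher and 5 lower.

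Without doxycycline the vectors differed little. Of 17192 genes, 8 passed the threshold by limma, 5 higher and 3 lower in MPH cells, none of them changed 2-fold, and 1399 had an unadjusted p under 0.05. The phospholipase gene PLAAT2 was at 714.8 ± 27.2 normalised counts in MPH and 428.5 ± 40.3 in hrGFPii cells, a log2 difference of 0.74. ITGB7, an integrin gene, was at 2692 ± 30.5 and 2072 ± 43.5; BASP1, ANXA1 and TPM4 were higher by 0.62, 0.51 and 0.23 on the log2 scale. ONECUT2 and FERMT1 were lower, with log2 differences of -0.56 and -0.57, as was the ribosomal pseudogene RPS27AP16, which is uncertain, at -0.88. The count was 1 without MPH uninduced replicate 1 and also without hrGFPii uninduced replicate 3, 5 without hrGFPii uninduced replicate 1, and between 14 and 19 with a pseudocount of 5, the filter at 50 or TMM. ONECUT2 passed in each of the 6 fits without a library of these groups, while each of the other 7 was lost in at least 2 of them. With equal totals 45.5% of the genes that differed were higher, against 62.5% on the deposited scale. B cell identity (camera adjusted p = 0.027) and mitochondrially encoded genes (adjusted p = 0.0211) were called upwards with no member past the threshold, and neither held with an estimated correlation (adjusted p = 0.269 and 0.504).

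With doxycycline in both, 8862 genes differed between MPH and hrGFPii cells, 4032 higher and 4830 lower in MPH cells, and 1540 differed at least 2-fold, 991 higher and 549 lower. HSF1 was higher by 2.06 on the log2 scale (adjusted p = 8.45e-13). DNAH6, RAB6B and DNM1 were higher by 3.85, 3.51 and 3.15, and THBS1 and SLCO4A1 lower, with log2 differences of -2.82 and -2.61. IRF4 and MYC differed by -1.49 and -1.46. All 14 plasma cell genes (camera adjusted p = 9.89e-11) and all 23 G2/M genes (adjusted p = 1.02e-13) were lower, while interferon-stimulated genes were not called, with 14 of 27 higher and 5 lower (adjusted p = 0.057). Of 18 lists called, all downwards, mitochondrially encoded genes, hypoxia with glycolysis, the NRF2 response, and stromal and epithelial markers were lost with an estimated correlation, at adjusted p-values of 0.42, 0.0692, 0.0737 and 0.0692. With equal totals 72.6% of the genes that differed were higher, against 45.5% on the deposited scale, and 915 differed at least 2-fold with the filter at 50.

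The inductions were compared gene by gene; they share no library. Of the 2233 genes called in hrGFPii cells, 84.1% were called in the same direction in MPH cells, while 18.7% of the 10055 called in MPH cells had the same call in hrGFPii cells. This made 662 genes higher in both, where independent lists would share 262.2, and 1217 lower in both, where independent lists would share 394.9. Both calls used the same estimate of the spread of a gene. Genes with a small spread are thus more readily called in both, which the numbers for independent lists do not allow for. Another 106 genes were called in opposite directions, where independent lists would give 648.9. The fold changes had a Pearson r of 0.336 and a Spearman rho of 0.432 across the 17192 genes, which are not independent replicates. Examples called in both are IRF4, MYC, CCND2, XBP1 and SLC7A5 among those lower, and DTX3L, IFIT5, OAS3 and DDX60 among those higher.

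**Figure D5:**
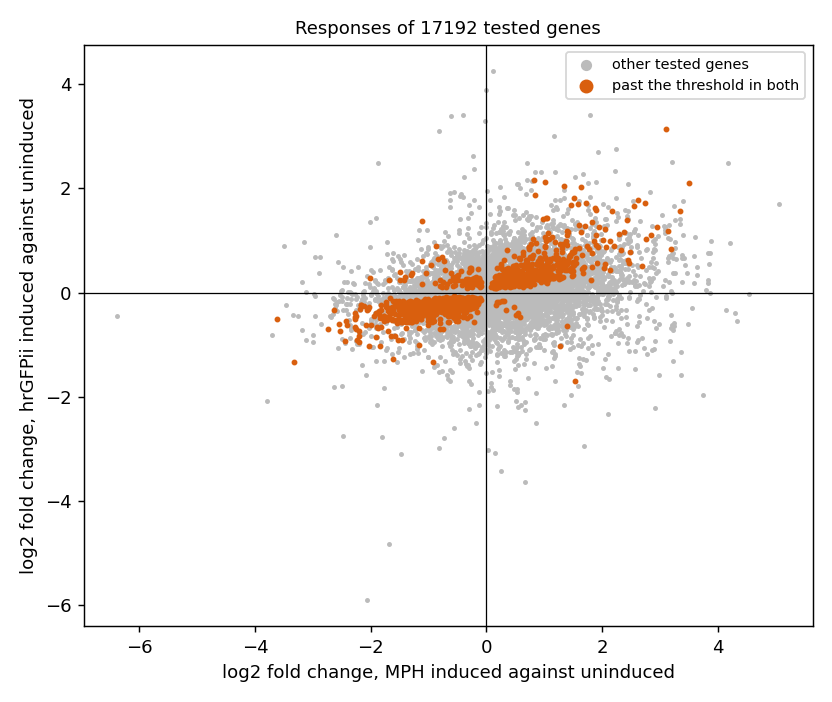
Log2 fold change of each tested gene in hrGFPii cells (vertical) against that in MPH cells (horizontal), induced against uninduced, with genes past the threshold in both shown in orange. The orange points comprise 662 genes higher in both, 1217 lower in both and 106 in opposite directions.

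MPH induction and the difference between uninduced cells share the MPH uninduced libraries. Their fold changes had a covariance of -0.0539 across genes, within the range of -0.0572 to -0.0427 that simulated unchanged groups gave, with a mean of -0.0489. The Pearson r was -0.208, outside the simulated range of -0.556 to -0.449 with a mean of -0.501. The simulated groups held no response to induction, and the spread of a real response brings r nearer to 0. The r values thus say nothing about differences before induction. The 3 shared libraries were too few to split. With the filter at 50 the covariance was -0.0198, within the range of -0.0222 to -0.0121 that unchanged groups simulated from those 13534 genes gave.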

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

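The shares of MPH RNA read from HSF1, IRF4, MYC and CCND2, and the splits of the libraries, were tests chosen only after the results were seen. Groups of 3 libraries were not searched for a library far from the others.

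By the test of the difference itself, the response to induction differed between MPH and hrGFPii cells for 6639 genes, 38.6% of those tested. It differed for 18 of the 25 lists and for 140 of the 162 named genes. Most named genes were picked by their tests for MPH induction or for this difference, so their share follows from that choice. The 106 genes called in opposite directions in the 2 inductions all passed the test of the difference too. Opposite calls in a shared fit make that nearly certain, so it adds no separate evidence. Among the named genes, TPM4 changed by -0.28 in MPH and 0.20 in hrGFPii cells on the log2 scale, HSPA1A by -0.12 and 0.29, DNAJB1 by -0.30 and 0.20, LTB by -2.02 and 0.28, TOP2A by -0.70 and 0.11, and BST2 by -0.68 and 0.16. With equal totals per library, HSPA1A changed by 0.15 in MPH cells and the calls of TPM4 (log2 change -0.01, adjusted p = 0.781) and DNAJB1 there were lost, while LTB, TOP2A and BST2 stayed opposite. With equal totals 108 genes were called in opposite directions, 46 of them among the 106, so which small changes count as opposite varies with the scaling.

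Of the 2233 genes called in hrGFPii cells, 84.1% nevertheless had the same call in MPH cells, though these were only 18.7% of the 10055 called there. RNA or cells of the MPH induced cultures in the hrGFPii induced libraries would carry HSF1 with them. The share of MPH RNA implied by HSF1 was 1.11% (limits -0.837 to 3.05). The falls of IRF4, MYC and CCND2 implied 32.3% (24.3 to 40.3), 46.1% (39.4 to 52.8) and 51.8% (45.6 to 58). Medians were 24.3% over the 782 genes that fell and 12.5% over the 1473 that rose at least 2-fold in MPH cells. The gap between HSF1 and these genes argues against such mixing. These limits are a normal approximation from the spread of the hrGFPii libraries alone, so they are too narrow for groups of 3. A trend shared through abundance, GC content and gene length is also argued against, since the Pearson r across 16928 genes was 0.341 before and 0.311 after these trends were removed. Doxycycline itself, and the expression of any transgene from the vector, may lie behind the shared part; they stay open and untested, since no untransduced cells with doxycycline were analysed here.

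For the interaction, 1 of 100 regroupings of the 12 libraries into 4 groups of 3, the real one, gave as many genes as the real 6639, and the highest other gave 2. None of the others kept the MPH induced libraries together, so the MPH response entered the spread within groups in each of them, and their low counts do not settle whether chance is excluded. When labels were exchanged only within each vector, 10 of 100 drawn splits out of 200 gave as many, the highest other with 7920 genes; each of these kept the MPH groups intact, and the highest that broke them gave 3, so this scheme does not settle it either. For the comparisons of 3 against 3 libraries, the 10 splits are too few for a share under 0.05. The real split, 1 of the 10 in each case, gave 10055 genes for MPH induction with a highest other of 2, 2233 for hrGFPii induction with a highest other of 1, 8 for the uninduced comparison with a highest other of 1, and 8862 for the induced comparison with a highest other of 1.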

How the results depend on the processing

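Rescaling to equal totals and thinning of reads were chosen after the data had been seen. The planned edgeR and DESeq2 fits were not run, because whole reads were not recovered. Most counts kept within 1.5 times of the reported value, and the cause was not tested where they did not, except that a filter of 50 tests fewer genes. With that filter, at least 2-fold changes numbered 1452 (834 up) for MPH induction, 58 for hrGFPii induction, 915 for the induced and 1 for the uninduced comparison, 19 genes passed in the uninduced comparison, and the covariance of MPH induction with the uninduced difference was -0.0198, where unchanged groups simulated with that filter gave -0.0222 to -0.0121. With only the compared groups, hrGFPii induction gave 1383 genes. The uninduced comparison gave 14 genes, 1 of them 2-fold, both with a pseudocount of 5 and with TMM, and 1 at 2-fold with no filter. With an estimated correlation 7 lists were called for hrGFPii induction.

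Leaving out a replicate gave 9049 to 9402 genes for MPH induction (2-fold 2013 to 2196), 1444 to 2478 for hrGFPii induction (64 to 128), 5913 to 6686 for the interaction (1086 to 1282), 1 to 10 for the uninduced (0 to 2) and 7791 to 8528 for the induced comparison (1290 to 1499).

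Equal totals shifted log2 changes by 0.269, 0.048, 0.22, -0.016 and 0.205 in the order MPH induction, hrGFPii induction, interaction, uninduced and induced. The direction reversed for HSPA1A (0.15), HSPA1B (0.13; interaction 0.0083), MT-ND3 (0.0667), MT-ND6 (0.0077), MT-ND4 (0.0369) and the mitochondrially encoded list (0.11), which follows from that shift. With fry the coactivator list had a direction opposite to camera, with a median of -0.0698.

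With the replicate number as a block, 10019, 2083, 6569, 9 and 8827 genes passed in that order, and no named gene changed its call. No list changed its call in MPH induction, hrGFPii induction or the interaction. Lists of the other comparisons were not tested under the alternative settings. Over all settings, 58 results of named genes and 23 of lists lost their call, and 2 and 24 gained it. Another 3143 and 998 stayed as they were, called in the same direction or not called, where the direction could differ. The numbers were not taken to pair the libraries: 18 same-number pairs correlated between -0.117 and 0.190 in their deviations from group means, 1 over 0.1, and in 14 of 36 comparisons a library was closest to that of its own number.

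Thinned to the shallowest library, 23975 ± 124 rows were above 0 in MPH induced libraries and 22382 to 22583 in the other groups on average, against 24579 and 22720 to 23041 before. Fewer reads must list more rows at 0, but the higher number in MPH induced libraries remained at equal estimated depth.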

Other observations

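The tests here were chosen only after the result was seen, except the sum over all olfactory receptor genes, which was written before. The gene families below were chosen after their values were seen, out of 152 families of at least 12 tested genes that share the letters of their symbols, tested with camera and adjusted over the families.

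For MPH induction 18 of the 152 families were called, 6 upwards and 12 downwards, and none with an estimated correlation, where the lowest adjusted p was 0.084. The 7 described here each had that adjusted p of 0.084. Of 16 intraflagellar transport (IFT) genes 12 rose and 0 fell (adjusted p = 0.00115), with a median log2 change of 0.50. Of 12 genes with EXOC symbols, taken by symbol alone and so not only exocyst subunits, 10 rose and 0 fell (adjusted p = 0.00479). Host genes of small nucleolar RNAs (SNHG) fell in 22 of 26 cases and rose in 3 (adjusted p = 2.64e-06), with a median log2 change of -0.92. Mitochondrial ribosomal proteins fell in 44 of 52 cases in the large subunit (MRPL; adjusted p = 3.56e-07) and 21 of 32 in the small (MRPS; adjusted p = 0.00242). Mitochondrial import genes (TIMM) fell in 15 of 16 cases (adjusted p = 4.97e-05). Of 67 genes with EIF symbols, likewise not only translation initiation factors, 50 fell and 8 rose (adjusted p = 4.03e-06). With equal totals 20 MRPL genes were lower and 10 higher, 10 and 10 MRPS genes with a median of -0.011, 11 and 1 TIMM genes, 32 and 16 EIF genes, and 21 and 3 SNHG genes, while 16 IFT and 12 EXOC genes were higher and 0 lower. In hrGFPii cells SNHG genes fell in 14 of 26 cases (adjusted p = 5.57e-08; 0.0913 with an estimated correlation).

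Constant genes of antigen receptors fell as well. All 7 tested immunoglobulin constant genes and all 3 tested T cell receptor constant genes fell at least 2-fold in MPH cells. Some had low values, so the sizes of their falls are uncertain. IGHG1 went from 10.7 to 1.89 normalised counts, IGHD from 23.1 to 8.83, IGHA2 from 40.8 to 9.56 and TRAC from 49.6 to 15.1. Of 7 tested immunoglobulin variable genes 5 fell and 2 did not pass, IGHV3-43 (log2 change -0.021, adjusted p = 0.968) and IGKV3D-20 (5.14 to 2.29 normalised counts, adjusted p = 0.0971). IGHM went from 21630 to 6527 normalised counts and IGKC from 2794 to 770.5, log2 changes of -1.73 and -1.86. In hrGFPii cells 3 of the 7 immunoglobulin constant genes passed, where IGHM changed by -0.17 (adjusted p = 0.0342) and IGKC by -0.42 (adjusted p = 0.000508). Several of these genes have near-identical copies, and their values are uncertain.

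Abundant genes fell and scarce genes rose after MPH induction. Of 265 genes with a mean above 20000 normalised counts, 247 fell and 2 rose, with a median log2 change of -0.53. Of 2425 tested genes with a mean up to 20, 469 rose and 114 fell, with a median of 0.41, but a gene could enter that bin by rising in MPH induced cells. With the filter and the bins taken from the hrGFPii libraries alone, 311 of 1553 genes up to 20 rose and 74 fell, with a median of 0.32, and 270 of 289 above 20000 fell and 2 rose. The Spearman rho with the mean was -0.352 across 17192 genes, against -0.144 for hrGFPii induction and 0.067 for the uninduced comparison.

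For this relation with abundance, GC content and gene length are argued against, since the median of the abundant genes was -0.59 once these trends were removed. How far the abundant genes fell cannot be told apart from the authors' scaling: with equal totals 74.0% of the 265 were still called lower, under the 75% set as the bound, with a median of -0.27, while a single factor per library leaves the difference between abundant and scarce genes as it is. Genomic DNA stays open too. The sum over 104 olfactory receptor genes changed 0.836-fold, but OR51B5 alone held 78.6% of it, so that sum says little; the 98 with a mean under 20 rose 1.30-fold (95% limits 1.15 to 1.48), between the bounds set. A broad change of transcription by the activation domains is a candidate explanation that was not tested.

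HSF1 rose after MPH induction and RELA did not. Transgene sequence counted on both genes is argued against by the log2 change of RELA, -0.32, or -0.05 with equal totals. The heat shock list as a whole did not rise, with a median of -0.34, or -0.08 with equal totals, where 7 of 25 were higher and 12 lower. This does not settle whether HSF1 was more active at heat shock genes, because the fall of abundant genes could mask a rise. Genes above 20000 normalised counts had a median of -0.53. Among the members, HSPA1A and HSPA1B were at 0.15 and 0.13 with equal totals. Transgene sequence counted on HSF1 alone may account for its log2 change of 2.09, and cannot be told apart from expression of the gene itself, because the values are per gene and not per exon.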
